A study of Caenorhabditis elegans with 2 samples.

How the data were processed

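The series holds ChIP-seq of the C. elegans transcription factor ELT-4 in whole late embryos, collected 3 hours after synchronization by egg bleaching, from a strain with an integrated transgene that expresses ELT-4 with a C-terminal GFP and FLAG tag. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP (a separate label field names elt-4 as the antibody), and the samples are 2 biological replicates of this single group. No other group was part of the design, so no comparison between conditions was made, and replicates were compared with each other and peaks with other regions of the same libraries.

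The authors deposited region lists in narrowPeak layout on builds ce10 and ce11. There was a list of 30000 regions called on each replicate alone and a list of 30000 regions called on both replicates pooled. A further list held the peaks of an irreproducible discovery rate (IDR) filter, a procedure designed to keep regions ranked alike by replicate lists. Here those peaks were exactly the pooled regions of highest signal, so single peaks were not all ranked alike by the replicates. Regions were called against a control file, per the notes deposited with the samples, which were read for provenance only; the aligner, the peak caller, their versions, the read filters and the IDR threshold are not given in the sources used here. The signal of each region is the value the authors' peak caller gave it, on a scale that is not stated, and it was used to describe, rank and match regions and, in the closing section, in a logistic model and a permutation test of median signal. The other column used holds −log10 of a q-value in the deposited lists. In the list of IDR peaks both columns are those of the pooled list, so they are not IDR values, and the p-value column, set to -1 throughout, was not used. No read counts or sequencing depths were used here, so the depth of each library is unknown, and a strong region cannot be told from a deeply covered one by these values alone. Signals were not scaled between the replicate lists, whose median signals were 16.4 in replicate 1 and 18.3 in replicate 2. An SD over the 2 lists can therefore include a difference in scale. The control library was not analysed here.

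All coordinates are on ce11 and 1-based, and the ce10 lists served only as an alternative. The reference was WBcel235 with its Ensembl annotation, which is the same assembly as ce11; every pooled region ended inside the reference chromosome of its name. The annotation on chromosomes I to V and X gave 19973 protein-coding genes, 612 tRNA genes and 346 snoRNA genes. Overlap meant at least 1 bp shared. A gene had a promoter peak when a summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated transcription start sites. Motif and GC content were read in the window of 100 bp on each side of the summit, 201 bp in all, and tRNA or snoRNA genes were searched within 500 bp of the summit.

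Shares among IDR peaks were compared with the 14937 regions of the pooled list that lay below its median signal and overlapped no IDR peak. Each comparison was a two-sided Fisher's exact test on counts of peaks, with an exact conditional 95% interval of the odds ratio and exact Clopper-Pearson 95% intervals of the shares. These intervals cover the counting of peaks only. Regions on 1 chromosome are not independent and come from the same 2 replicates, so the p-values do not measure variation between animals. The 4 planned shares (promoter, TGATAA motif, X chromosome and tRNA gene) were adjusted together by the Benjamini-Hochberg method, as were the 17 gene lists. Genes of a list with a promoter peak were set against all other protein-coding genes. Spearman's rho between replicates was computed across peaks, which are not independent replicates, with no p-value and with a Fisher z 95% interval.

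The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are those nearest to the 10 IDR peaks of highest signal, the 7 endoderm GATA factors, and at most 4 members of each list with a promoter peak. The lists were endoderm GATA factors, other GATA factors, intestine structure and function, vitellogenins, transcription factors with roles in the intestine, pharynx, body wall muscle, epidermis, neurons, germline, cytosolic ribosomal proteins, V-ATPase subunits, C-type lectins, cytochrome P450s, UDP-glucuronosyltransferases, nuclear hormone receptors and cuticle collagens. Every listed gene was found in the annotation. The cuticle collagen list held every annotated gene whose symbol is col- followed by a number, so collagen genes with other symbols were outside it.

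The alternatives were the ce10 lists, stricter or longer peak lists, each replicate's own strongest regions, other overlap rules, promoter windows, motif windows, motifs, distances and backgrounds, assignment to the nearest start site, and other windows around elt-4. Chosen after seeing the data were the snoRNA share and its alternatives, the other RNA classes, assignment by gene body, the rank correlation over all pooled regions, the location classes, merged overlapping peaks, leaving out 8 narrow regions, uniform genome positions as background, regions with at least 95% unique 36-mers, and matching the tRNA share by GC content and stratifying the tRNA and TGATAA shares by it. For matching, each IDR peak was paired with 1 background region of the same promoter location and a GC content within 2 percentage points, which left 334 pairs and 8 peaks without a partner. Stratified odds ratios were Mantel-Haenszel estimates over bins of 5 percentage points of GC content and promoter location. Repeated sequence was measured as the percentage of 36-mers in the window that occur more than once in the genome on either strand.

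The tests were checked on simulated peak sets of 342 regions drawn from 15000 weak regions. With a true odds ratio of 2, the promoter, TGATAA and X chromosome tests called 100 of 100 draws and the tRNA test 39 of 100; at an odds ratio of 4 the tRNA test called 96 of 100. With no effect, the calls were 6, 5 and 2 of 100 draws for promoter, TGATAA and X chromosome, and 0 of 100 for tRNA genes. Simulated peaks and their background came from the same weak regions, with no GC difference planted. The check therefore does not show how the tests behave when peaks and background differ in GC content. With 3 intestine genes planted as promoter peaks, the list test called 20 of 20 draws. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.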

Results

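ELT-4 is a small GATA-type zinc finger protein of C. elegans, encoded next to elt-2, the main GATA factor of the intestine. Regions were called from ChIP-seq of a GFP-tagged ELT-4 in whole late embryos, in 2 biological replicates of 1 group. The question was where in the genome the tagged protein is found at this stage. Each replicate list and the pooled list held 30000 regions, most of them far from any usual threshold: 1279 of the 30000 pooled regions had a q-value of at most 0.05. The IDR filter left 342 peaks, whose q-values, as deposited, ran from 0.00234 to 0.0126. Sequencing depth is unknown.

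The strongest IDR peaks lay in intergenic sequence or in introns, and 4 of the 10 strongest were within 500 bp of a snoRNA or tRNA gene. The peak of highest signal, 346, spanned III:8043809-8044115 in intergenic sequence, 524 bp upstream of K12H4.5, with a signal of 173 ± 5.03 in the replicate lists (mean ± SD, n = 2). The second lay at III:3499970-3500135, in an intron of M01F1.8 and 959 bp upstream of M01F1.9, at 161 ± 59.4. The third was intergenic at I:933368-933676, at 168 ± 22.3, and 4966 bp from nas-30, which encodes an astacin-type metalloprotease; 54.8% of the 36-mers in its window occurred more than once in the genome. The fourth, at V:12303519-12303748, lay in an intron of frm-7, within 500 bp of the snoRNA genes C51F7.3 and C51F7.4, at 116 ± 31.9, and its nearest start site was that of F55C5.17. Of the other 6 of the 10 strongest, a pair of overlapping peaks lay upstream of eel-1, a ubiquitin ligase gene, from IV:3050371 to IV:3051047, at 93.8 ± 4.34, and 68.1% and 83.7% of the 36-mers in their windows were repeated. The peak at I:8259315-8259784 lay within 500 bp of the snoRNA gene ZK265.10, with sre-23, a chemoreceptor-family gene, as the nearest gene (93.3 ± 6.99). That at II:11960754-11960931 lay within 500 bp of the snoRNA gene W03C9.9, nearest to W03C9.1 (83.2 ± 20.98). The peak at III:4568681-4568806 lay 41 bp upstream of idhg-1, a mitochondrial isocitrate dehydrogenase subunit gene, at 84.1 ± 3.66. The peak at X:9743367-9743836 lay in an intron of him-4, which encodes hemicentin, within 500 bp of 2 tRNA genes, at 87.0 ± 1.58, and its nearest start site was that of F15G9.5. Among these 10 peaks, those nearest to K12H4.5, nas-30 and idhg-1, of rank 1, 3 and 7, had TGATAA within 100 bp of the summit. The others did not.

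The replicates shared part of their strongest regions. Of the 342 strongest regions of replicate 1, 96 (28.1%) overlapped one of the 342 strongest of replicate 2. Over the pooled regions, 153 overlapped both sets, where independent sets would give 8.89, an odds ratio of 33.7 (95% interval 26.98 to 42.0; Fisher's exact test, two-sided, p = 2.0e-148). The sets of 342 overlapped 523 and 510 pooled regions, so a replicate region could count more than once, which the p-value ignores. GC content averaged 53.1% and 52.4% in the sets of replicate 1 and 2, against 40.8% in the weak background regions. Overlap beyond this shared GC content was not tested. Of the 342 IDR peaks, 186 (54.4%) overlapped the strongest 342 of replicate 1, 212 (61.99%) those of replicate 2, 98 (28.7%) both and 42 (12.3%) neither. The IDR peaks were exactly the 342 pooled regions of highest signal, so a peak could be in the list without like ranks in the replicates. For example, the peak of pooled rank 109 ranked 16 in replicate 1 and 7813 in replicate 2. Across the IDR peaks, Spearman's rho of the signal in replicate 1 and replicate 2 was -0.109 (95% interval -0.212 to -0.00277). Selection by pooled signal, which rose with the signal of replicate 1 (rho 0.512) and of replicate 2 (rho 0.613) across these peaks, lowers this rho by construction, so it does not measure how well the replicates matched. Across the 16769 of 30000 pooled regions with a region in both replicate lists, a set chosen after seeing the data, rho was 0.312. That set leaves out regions missing from either list, so its rho is not free of selection either.

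**Figure D1:**
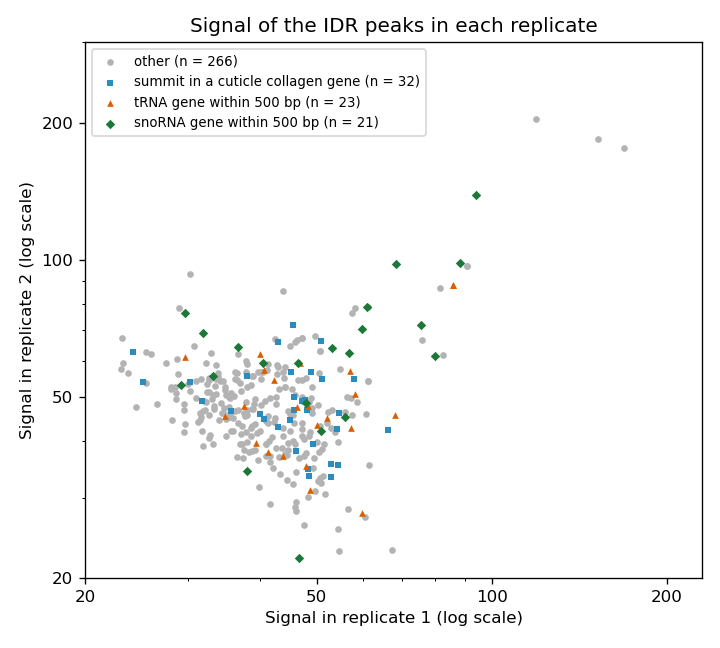
Signal of the 342 IDR peaks in replicate 1 (x axis) and replicate 2 (y axis), as given by the authors' peak caller in each replicate list, on log scales; each point is 1 peak. Orange triangles mark 23 peaks within 500 bp of a tRNA gene, green diamonds 21 within 500 bp of a snoRNA gene, blue squares 32 with the summit in a cuticle collagen gene and grey circles the other 266; the points are the top of the pooled list, so their rho of -0.109 is lowered by that selection.

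tRNA and snoRNA genes were over-represented near the IDR peaks, though the test for tRNA genes did not pass in unique sequence. A tRNA gene lay within 500 bp of 23 of the 342 peaks (6.73%, 95% interval 4.31 to 9.92) and of 148 of the 14937 below-median regions (0.991%). The odds ratio was 7.20 (95% interval 4.37 to 11.4; Fisher's exact test, two-sided, p = 5.0e-12, adjusted over the 4 planned shares p = 2.0e-11). A snoRNA gene, a class examined after the strongest peaks had been seen, lay within 500 bp of 21 peaks (6.14%) and of 60 below-median regions (0.402%). Its odds ratio was 16.2 (95% interval 9.25 to 27.4; Fisher's exact test, two-sided, p = 4.9e-17). Against regions matched in GC content and promoter location, the odds ratio was 7.38 (95% interval 2.17 to 39.0) for snoRNA genes, with 3 of 334 matched regions near one, and 24.6 (95% interval 3.94 to 1017) for tRNA genes, with 1 of 334. Stratified by GC content and promoter location over all below-median regions, it was 14.8 (95% interval 7.63 to 28.6) for snoRNA genes and 11.8 (95% interval 6.88 to 20.2) for tRNA genes, so the classes were not ranked by these values. A snoRNA gene lay near 7 of the 20 strongest peaks, and 12 of the 21 snoRNA peaks lay in introns of protein-coding genes, among them pxn-1, catp-8 and mpk-2 (named after their values were seen). None of the 23 tRNA peaks lay in coding sequence, 8 lay in introns, and 15 were on the X chromosome. In 19 of the 23 tRNA windows, but in 0 of the 21 snoRNA windows, over 5% of the 36-mers occurred more than once in the genome. Among regions with at least 95% unique 36-mers, an alternative chosen after seeing the data, a tRNA gene lay near 4 of 289 peaks and 95 of 13519 below-median regions. There the odds ratio was 1.98 (95% interval 0.526 to 5.30; Fisher's exact test, two-sided, p = 0.154) for tRNA genes and 18.2 (95% interval 10.3 to 30.9) for snoRNA genes.

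TGATAA, the GATA-type site searched for here, was less frequent in IDR peaks than in weak regions. The shares in promoters and on the X chromosome did not differ detectably between all peaks and those regions. At least 1 TGATAA lay within 100 bp of 19 of the 342 summits (5.56%, 95% interval 3.38 to 8.54), against 14.1% of the below-median regions. The odds ratio was 0.359 (95% interval 0.213 to 0.571; Fisher's exact test, two-sided, p = 7.7e-07, adjusted p = 1.5e-06). Against the 334 regions matched in GC content and promoter location the odds ratio was 0.947 (95% interval 0.468 to 1.91; Fisher's exact test, p = 1.0). GC content averaged 53.3% ± 7.09 (SD over 342 peaks) in the peaks and 40.8% ± 6.76 in the below-median regions. Of 2080 hexamers, 481 were more frequent in the peaks and 457 less frequent at an adjusted p under 0.05 by Fisher's exact test, led by CGCCGC (22.5% of peaks, 5.62% of below-median regions) and AAAAAT (20.2% and 53.7%). Summits lay in a promoter window for 93 peaks (27.2%) and for 26.7% of the below-median regions, an odds ratio of 1.02 (95% interval 0.796 to 1.31; Fisher's exact test, two-sided, p = 0.853, adjusted p = 0.853). Of 10000 uniform genome positions, a background added after seeing the data, 26.5% lay in such a window. Against these positions the odds ratio was 1.04 (95% interval 0.804 to 1.32, Fisher's exact test, two-sided, p = 0.803). No excess of promoters over random positions was thus detectable. The X chromosome held 51 peaks (14.9%) and 16.8% of those regions, an odds ratio of 0.866 (95% interval 0.628 to 1.17; Fisher's exact test, two-sided, p = 0.380, adjusted p = 0.507). The strongest regions of replicate 1 alone, without replicate 2, gave an odds ratio of 1.03 for the X chromosome. Among regions with at least 95% unique 36-mers it was 0.635 (Fisher's exact test, two-sided, unadjusted p = 0.0116), with 34 of 289 peaks on X, and for promoters it was 0.963. By annotation, 140 summits (40.9%) lay in coding sequence, 97 (28.4%) in introns and 73 (21.3%) in intergenic sequence.

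**Figure D2:**
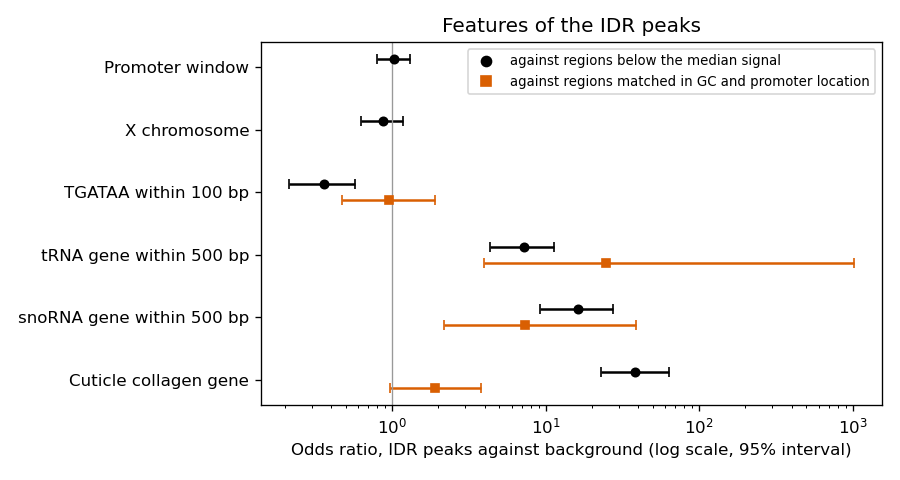
Odds ratio of each feature in the 342 IDR peaks (x axis, log scale) with its exact 95% interval, against the 14937 pooled regions below the median signal (black circles) and, for 4 features, between 334 IDR peaks and 334 regions matched in GC content and promoter location (orange squares). TGATAA moved from 0.359 to 0.947 and cuticle collagen genes from 38.4 to 1.89 with matching, while the matched intervals of tRNA genes (3.94 to 1017) and snoRNA genes (2.17 to 39.0) stayed above 1.

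Of the genes fixed as intestinal, hlh-30 was the only one with a promoter peak, and it had none among the strongest regions of replicate 2 alone, without replicate 1 (0 of 11 in its list). Of the 19973 protein-coding genes, 114 had a promoter peak. These included 0 of 7 endoderm GATA factors, 0 of 4 other GATA factors, 0 of 35 genes of intestine structure and function, 0 of 6 vitellogenins and 1 of 11 transcription factors with roles in the intestine. That 1 was hlh-30, a regulator of autophagy and lysosomal genes, with a peak at IV:4028033-4028502 in an intron, 141 bp upstream of a start site, at 44.0 ± 5.03 (mean ± SD, n = 2). Among genes of other tissues, body wall muscle had 2 of 22: unc-54, a muscle myosin heavy chain gene, at I:14863410-14863879 (42.4 ± 6.27), and act-4, an actin gene, at X:4960231-4960700 (41.8 ± 12.2), both in intergenic sequence. Body wall muscle had the lowest p of the 17 lists (Fisher's exact test, p = 0.00692, adjusted p = 0.118). No list passed after adjustment by Fisher's exact test with the Benjamini-Hochberg method, and 1 of 17 had an unadjusted p under 0.05. Without replicate 2, body wall muscle had 1 of 22 genes (Fisher's exact test, p = 0.116) and 0 lists had an unadjusted p under 0.05. With a window of 500 bp upstream and 100 bp downstream, body wall muscle passed (2 of 22, Fisher's exact test, adjusted p = 0.0381), and over all alternatives its adjusted p ran up to 1.0. For the 35 intestine genes 0.200 genes with a promoter peak would be expected at the rate of all genes, so a shortage in this list was not detectable. The other lists with members were cytosolic ribosomal proteins (2 of 78, rpl-17 and rps-24), C-type lectins (1 of 240, clec-126, whose peak lay within 500 bp of 2 tRNA genes), cytochrome P450s (1 of 74, cyp-33C2), nuclear hormone receptors (2 of 269, nhr-217 and nhr-239) and cuticle collagens (2 of 156, col-46 and col-72). The lists of pharynx (14 genes), epidermis (17), neurons (27), germline (19), V-ATPase subunits (20) and UDP-glucuronosyltransferases (67) had 0 members with a promoter peak.

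The cuticle collagen genes with a col- symbol, which encode structural proteins of the exoskeleton, had more peaks than other genes under wider assignments. With a promoter window of 2000 bp upstream and 500 bp downstream, 10 of the 156 genes had a peak (Fisher's exact test, adjusted p = 1.7e-04). By nearest start site 34 of the 156 genes (21.8%) had a peak, against 295 of 19817 other genes (Fisher's exact test, p = 1.8e-28, adjusted p = 3.1e-27). By gene body, an assignment added after seeing the data, 33 of 156 had a summit inside the gene (Fisher's exact test, p = 3.1e-31, adjusted p = 5.3e-30); over all assignments and peak sets tried, the adjusted p of this list ran from 5.3e-30 to 1.0. Those summits belonged to 32 peaks, all in coding sequence, with pooled signals of 78.9 to 123; the strongest, named after their values were seen, lay in col-122 (58.7 ± 18.5, n = 2) and col-91 (58.6 ± 10.7, n = 2). GC content in these windows averaged 60.4% ± 4.59 (SD over 32 peaks). Against regions matched in GC content and promoter location, 29 of 334 peaks and 16 of 334 regions lay in a collagen gene, an odds ratio of 1.89 (95% interval 0.970 to 3.80), and the stratified odds ratio was 1.84 (95% interval 1.004 to 3.38). By nearest start site the intestine list had 3 of 35 genes with a peak (Fisher's exact test, p = 0.0196, adjusted p = 0.0835, the lowest of its alternatives, the others up to 1.0). These genes, named after their values were seen, were act-5, an intestinal actin gene, and the transporter genes haf-9 and wht-2. The act-5 summit lay in coding sequence. The haf-9 peak lay in an intron of haf-9, within 500 bp of the snoRNA gene ZK484.9. The wht-2 peak lay outside wht-2, in an intron of catp-8 and 3880 bp from the wht-2 start site. It was within 500 bp of the snoRNA gene C10C6.8.

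None of the 7 endoderm GATA genes had an IDR peak in its promoter window, and the region around elt-4 itself held few regions of any strength. Within 5 kb of elt-4 (X:10475527-10475959), elt-2 (X:10481240-10483441) and med-1 (X:12430609-12431133) the pooled list had 0 regions. Within 5 kb of end-3, which specifies the endoderm, the strongest pooled region had a signal of 66.7, rank 876 of 30000 and a q-value of 0.0246. For end-1 that region ranked 2122 (signal 55.5, q-value 0.107), for elt-7, which acts beside elt-2 in the intestine, 9574 (36.2, q-value 0.495) and for med-2 18356 (27.8, q-value 0.736). In the 50 kb centred on elt-4 there was 1 pooled region (exact Poisson 95% interval 0.0253 to 5.57) and 0 IDR peaks. The same window held 1 region of the replicate 1 list and 5 of the replicate 2 list. In 100 kb there were 13 pooled regions, against a median of 29 over windows of that size. The median of the 2002 windows of 50 kb in the genome was 14 pooled regions, 99.1% of them held more than 1, and 85.3% held 0 IDR peaks. The strain carries extra copies of the tagged locus, and their effect on region calls around elt-4, with elt-2 close by, was not tested. Few regions there therefore do not show that the protein was absent.

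**Figure D3:**
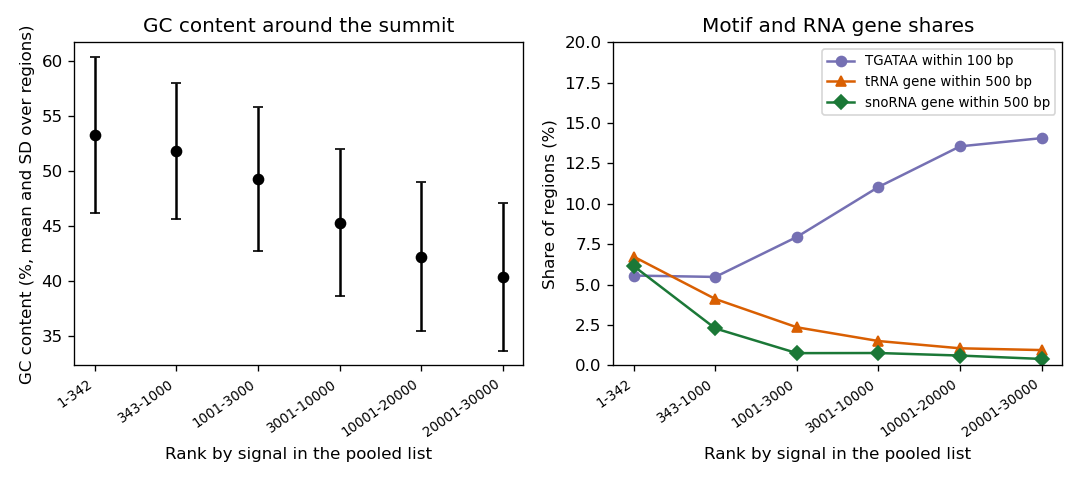
Left, mean GC content (%) around the summit with its SD over regions; right, share of regions (%) with TGATAA within 100 bp, a tRNA gene within 500 bp or a snoRNA gene within 500 bp; both by rank of signal in the pooled list, where ranks 1 to 342 are the IDR peaks. From the first class to the last, GC content went from 53.3% to 40.4%, TGATAA from 5.56% to 14.1%, tRNA genes from 6.73% to 0.940% and snoRNA genes from 6.14% to 0.390%.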

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

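Tests chosen only after the results were seen are the gene body assignment, the rank correlation over all pooled regions, the Mantel-Haenszel estimates, the matched tRNA share, merged or narrow peaks, uniform positions, unique sequence and all settings of the snoRNA share. The promoter share stayed near 1 in 10 alternatives (odds ratios 1.01 to 1.23), the overlap of the replicates stayed past its threshold in 5 (17.1 to 52.1), and so did the tRNA share in 11 (4.84 to 24.6) and the snoRNA share in 12 (7.38 to 31.0). Among regions with at least 95% unique 36-mers the tRNA share lost its call (1.98). There the X chromosome share passed an unadjusted threshold (0.635) and the promoter share crossed 1 (0.963). This restriction removes repeats by construction. With it, peaks on X went from 51 to 34 and tRNA peaks from 23 to 4, and 15 of the 23 tRNA peaks lay on X. Removed tRNA peaks were thus part of the X peaks lost, and other causes were not tested. The list of the 342 strongest pooled regions equals the IDR peaks, so that alternative moves nothing by construction. The TGATAA share kept its direction and side of the threshold in 12 alternatives (0.251 to 0.463), but not with GC content held fixed: the odds ratio was 0.947 with matched regions and 0.913 with stratification. The X chromosome share, past no threshold, ranged from 0.846 to 1.03 without one replicate or the other, crossing 1 without replicate 2; the cause was not tested. Rank agreement over the 16769 of 30000 pooled regions with a region in both replicate lists was 0.312, with regions missing from either list left out. Among the IDR peaks it was -0.109, a value that selection by pooled signal lowers by construction. The IDR peaks numbered 355 on ce10, 171 among the stronger part by construction, and 186 to 212 when required to be among the strongest regions of a single replicate. By Fisher's exact test with Benjamini-Hochberg adjustment 0 gene lists passed with the promoter window (1 at an unadjusted p under 0.05), while 1 list passed with the 500 bp window (body wall muscle), 1 with the 2000 bp window and 1 by nearest start site (both cuticle collagens), and 3 by gene body (cuticle collagens, neurons and transcription factors with roles in the intestine); the cause was not tested. Around elt-4 the density of pooled regions per 10 kb was 0.2 in 50 kb, 0 in 20 kb and 1.3 in 100 kb; the cause was not tested. Depth is unknown, so it limits what the absence of a peak at a gene can mean.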

Other observations

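The other RNA classes, the locations, the gene body lists, the collagen share against below-median regions, the separate tests of tRNA and snoRNA genes in unique sequence, the share of tRNA and snoRNA peaks with TGATAA and the Mantel-Haenszel estimates were chosen only after the results were seen. Beyond tRNA and snoRNA genes, miRNA genes lay within 500 bp of 7 of the 342 IDR peaks and 57 of the 14937 below-median regions, an odds ratio of 5.45 (95% interval 2.08 to 12.1; Fisher's exact test, adjusted over 9 classes p = 0.00124). Genes annotated as ncRNA lay near 57 peaks (16.7%) and 8.12% of those regions, an odds ratio of 2.26 (Fisher's exact test, adjusted p = 1.3e-06). piRNA genes lay near 3 peaks (0.877%) and 2.38% of those regions, an odds ratio of 0.362 (Fisher's exact test, adjusted p = 0.126). For snRNA genes the odds ratio was 1.37 and for pseudogenes 0.750, with adjusted p of 0.677 and 0.647 by Fisher's exact test, while lincRNA and rRNA genes lay near 0 peaks (adjusted p = 0.723 and 1.0 by Fisher's exact test). No summit lay in a 3' UTR, against 2.50% of the below-median regions (Fisher's exact test, adjusted over 7 locations p = 0.00341). The RNA classes beyond tRNA and snoRNA genes and the locations were not compared with regions matched in GC content. The peaks averaged 53.3% GC and the below-median regions 40.8%, so an effect of GC content on these differences was not tested. By gene body the neuron list had 4 of 27 genes with a summit (Fisher's exact test, adjusted p = 0.00281); these, named after their values were seen, were cha-1 and unc-17, which act in acetylcholine transmission and share 1 peak, the kinesin gene unc-104, and cat-1, a monoamine transporter gene whose peak lay within 500 bp of a tRNA gene. The adjusted p of this list was up to 1.0 under other assignments. The transcription factors with roles in the intestine had 2 of 11, hlh-30 and daf-16 (daf-16 named after its value was seen; Fisher's exact test, adjusted p = 0.0448, up to 1.0 under other settings). The test by gene body took no account of gene length or GC content, so neither list was compared with genes of like length.

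The excess of tRNA and snoRNA genes among the IDR peaks was set against 3 explanations. GC content as the whole explanation is argued against, since 44 of 334 peaks and 4 of 334 matched regions lay at such genes, an odds ratio of 12.5 (95% interval 4.46 to 48.4). In windows with at least 95% unique 36-mers the odds ratio was 8.27 (5.10 to 12.9) for the classes together and 18.2 (10.3 to 30.9) for snoRNA genes, which argues against reads shared between gene copies for snoRNA genes, but for tRNA genes it was 1.98 (0.526 to 5.30), so shared reads stay open there. Binding at TGATAA sites is argued against for most of these peaks, since 4 of 44 (9.09%, exact 95% interval 2.53 to 21.7) had the motif within 100 bp. Whether it plays a part at those 4 stays open, with an odds ratio of 1.57 (0.371 to 5.02) against the 334 regions matched to the IDR peaks as a whole. GC content averaged 52.5% in those regions and 48.6% in the 44 peaks, so it was not held fixed in this comparison. A signal that active small RNA genes give in ChIP whatever the factor may also contribute; it was not tested, because neither a control library nor another factor was analysed here.

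The concentration of IDR peaks in cuticle collagen genes may follow GC content to a large part. The odds ratio of 38.4 (95% interval 23.0 to 63.6) against below-median regions was 1.89 (0.970 to 3.80) against regions matched in GC content and promoter location, and 1.84 (1.004 to 3.38) when stratified by both. Shared reads between collagen genes are argued against for the excess over below-median regions, since the odds ratio in windows with at least 95% unique 36-mers was 55.6 (31.3 to 99.2). That comparison was not matched in GC content, so it does not test shared reads for an excess beyond GC content. A smaller excess beyond GC content stays open, as the matched interval includes 1 while the stratified interval lies just above it, and no biological explanation was tested.

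The lower frequency of TGATAA in IDR peaks is in line with an effect of GC content, since the odds ratio of 0.359 became 0.947 (95% interval 0.468 to 1.91) against matched regions. A hypothesis that TGATAA binding is spread over regions below the IDR threshold was tested across all 30000 pooled regions, in a logistic model with GC content. The coefficient of TGATAA per doubling of signal lay above 78.0% of 59 other hexamers of the same base composition, short of the 95% set as the bound, and its 95% interval was -0.0687 to 0.111 in log odds, so the hypothesis was neither excluded nor borne out. A second hypothesis, stronger signal at intestinal promoters, gave a median of 29.3 for the 14 intestine genes with a pooled region in the promoter window against 31.8 for other genes (permutation test, two-sided, p = 0.411), which leaves it open too.

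The 8 regions narrower than 470 bp all ranked among the 12 strongest. The median share of repeated 36-mers in their windows was 0%, and 2 of the 8 held any. Of these 8, the regions of rank 1, 3 and 7 had TGATAA within 100 bp of the summit and the others did not. An excess of the motif in this small set was not tested.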
